A study of Mus musculus with 8 samples.

How the data were processed

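RNA was measured by sequencing in 8 libraries of whole mouse ventricle, the lower chambers of the heart, from C57BL/6J mice at postnatal days 3, 6, 12 and 24 (P3, P6, P12 and P24), with 2 libraries per stage. Per the labels' protocols, total RNA was extracted with QIAzol and its DNA digested. RNA with an integrity score of at least 7 was selected for poly(A) tails, and libraries were made with a NEBNext Ultra RNA kit. Stage and replicate number were taken from the library titles. Nothing in the labels says that replicates came from separate animals or litters, so p-values measure only the spread between these libraries.

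The authors deposited 1 table for all libraries, which holds 21970 genes with Ensembl identifiers, all of them protein-coding. Per the file headers, the deposited signal is a normalized count per gene. The authors also deposited FPKM values. Within a gene the ratio of FPKM to normalized count was the same in every library, so the FPKM values were not tested separately. The submitters' processing notes name Trim Galore 0.6.4, STAR 2.7.3a, HTSeq 0.11.2, DESeq2 1.32.0 and the mouse assembly GRCm39, without saying what each was used for. The gene annotation release and the strand setting of the counting were not given in the sources used here, so genes that overlap another gene, or that share reads with a near-identical copy such as Acot1 and Acot2 or mitochondrial transcripts with nuclear copies, are uncertain. The reference annotation at hand was of another assembly, so no coordinates are given; that annotation was used for symbols of 12 genes and for GC content of transcripts. Of the genes in the table, 4321 had a value of 0 in every library.

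Each library's normalized counts were whole multiples of the value of 1 read: with a tolerance of 0.001, 100% of the values came out as whole reads. The recovered totals in protein-coding genes lay between 23375967 and 28745112 reads per library. At these depths a count of 0 allows a share of up to 1.28e-05% in the shallowest library (3 reads of the total), which covers counting error only.

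Since the table holds normalized values and not counts, the test set for that case was used in place of edgeR: limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with the trended variance of eBayes, stage as a factor and no replicate term. Genes were kept where the value was at least 10 in at least 2 libraries, which left 14055. All 8 libraries entered 1 fit, with 4 residual degrees of freedom and 4.83 prior degrees of freedom. A gene changed where its Benjamini-Hochberg (BH) adjusted p was below 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The contrasts were each successive step, P3 to P24, P3 to P12 and P6 to P24, with a joint F test over the stages. Peak genes were higher at P6 or at P12 than at both P3 and P24, each contrast past the threshold, and trough genes were lower than both.

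Gene lists were tested with camera, which compares a list with all other genes, with a preset correlation of 0.01; BH adjustment covered 35 lists with at least 4 measured members and 4 contrasts, 140 tests. With the preset correlation 59 of the 140 passed. With a correlation estimated from the data the count was 0, against 37 with fry, a test of whether a list's genes move together that does not compare them with other genes. The design, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined; the others are named as added later. The rule took, for each successive step and for P3 to P24, the 5 largest rises and 5 largest falls among changed genes with a mean of at least 100 in 1 of the stages and a named symbol, the changed members of a list with the 2 largest rises and the 2 largest falls, all members of the retinoic acid and cell cycle inhibitor lists, the 10 peak genes with the largest smaller difference, list members among peak and trough genes, and Y-linked genes. Some genes that the rule names are not reported here. Genes named to complete a count of 5 or fewer were chosen after their values were seen, as were the atrial genes Myl7, Myl4 and Sln and the mitochondrial gene mt-Co2.

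The fit was tested on simulated data for the step from P3 to P6, with counts drawn from each gene's mean over all libraries and its estimated dispersion, over 13852 genes. limma recovered 42 of 49 genes (85.7%) simulated with a log2 change of -2, 25 of 50 at -1, 32 of 50 (64%) at 1 and 50 of 50 at 2. It called 17 of 13652 unchanged genes, and 1 gene when none was changed. Beside the recovered genes, those 17 are a larger share of the calls than the nominal 0.05. The simulation gave each gene the same dispersion at every stage and the same change at P6, P12 and P24. It therefore does not cover the wider spread of the P6 pair (median absolute log2 difference 0.39 against 0.118 to 0.154).

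The alternatives were quantile normalization, scaling by library size alone, no filter and a stricter filter (mean of at least 50), pseudocounts of 0.5 and 5, DESeq2 1.42.0 and limma-voom on the recovered reads, the replicate number as a block, leaving out each library, fitting only the 4 libraries compared, and a test against a log2 change of 1. Added after the data were seen were edgeR 4.0.16 on the recovered reads, a term for Y-linked reads, the removal of each library's trend with gene length and with GC content, and fits without both P6 libraries or without the pair of libraries with high atrial genes. The edgeR quasi-likelihood test on the recovered reads called 99 genes from P3 to P6, 347 from P6 to P12, 2173 from P12 to P24 and 5151 from P3 to P24.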

Results

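Whole ventricles of C57BL/6J mice, a common inbred laboratory strain, were profiled by poly(A) RNA sequencing at P3, P6, P12 and P24, with 2 libraries per stage. The series asks how the ventricle's transcripts change through the early postnatal period, in which heart muscle cells leave the cell cycle and mature, and its title names the retinoic acid signal. Values are the authors' normalized counts, given as means ± SD over the 2 libraries of a stage. Reads in protein-coding genes numbered 23752999 and 23691022 at P3, 25434953 and 23375967 at P6, 27115890 and 28745112 at P12 and 23806610 and 26478665 at P24. The first principal component of the log2 values carried 62.3% of the variance. Replicates differed by a median absolute log2 difference of 0.154 at P3, 0.39 at P6, 0.146 at P12 and 0.118 at P24. The P6 libraries lay farthest apart, with 1075 genes more than 2-fold apart against 407, 221 and 310 at P3, P12 and P24. Reads of 4 Y-linked genes numbered 5722 in P6 replicate 1, 7182 in P12 replicate 1 and 5260 in P24 replicate 2, and at most 4 in each of the other libraries, so both P3 libraries were among those with at most 4. Contrasts with P3 therefore differ in Y-linked reads as well as in stage. With a term for Y-linked reads, 84 of the 118 genes called from P3 to P6 and 4692 of the 5187 from P3 to P24 were called again.

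Over the whole span from P3 to P24, most cell cycle genes and 11 of 22 fetal muscle isoforms fell, while most genes of antigen presentation and interferon response and 17 of 33 adult muscle genes rose. Tnni1 (ENSMUSG00000026418), the slow skeletal troponin I of the fetal heart, dropped from 51900 ± 10250 (SD, n = 2) to 30.8 ± 3.36 (SD, n = 2), a log2 change of -10.66 ± 0.54 (SE) (limma, BH-adjusted p = 2.57e-06). Dlk1, an imprinted gene of fetal growth, fell from 1128 ± 316 (SD, n = 2) to 5.85 ± 1.31 (SD, n = 2) (limma, BH-adjusted p = 8.44e-07). Igf2bp1, a fetal RNA-binding protein, fell (log2 change -6.80), as did Plppr1 (-5.89) and the olfactory receptor gene Olfr608 (-5.75). Ces1d, a carboxylesterase of lipid metabolism, rose from 21.5 ± 0.519 (SD, n = 2) to 4633 ± 424 (SD, n = 2) (log2 change 7.68 ± 0.56 (SE)), and Mgl2, a lectin of macrophages, from 3.18 ± 2.96 (SD, n = 2) to 546 ± 86.6 (SD, n = 2). Retnla and the chemokine gene Cxcl14 were at 0 in both P3 libraries and reached 111 ± 47.7 (SD, n = 2) and 111 ± 12.1 (SD, n = 2), so no fold change is given for them. In all, 5187 of 14055 genes changed, 2623 rising and 2564 falling, and 2819 of them changed at least 2-fold. Scaled by library size alone, 1511 of 6520 changed genes rose (23.2% against 50.6%), with the median gene shifted by -0.35 on the log2 scale. Leaving out 1 library gave 3189 and 3410 changed genes without P3 replicates 1 and 2, 7819 and 7822 without P6 replicates 1 and 2, and 3063 and 3119 without P24 replicates 1 and 2. Without both P6 libraries the count was 7819, and against a log2 change of 1 it was 1059. Of 117 named calls 92 held in all 8 fits with a library left out.

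Transcripts of cell division fell together from P3 to P24. Of 48 S phase genes, which serve DNA replication, 45 fell (46 adjusted over the list alone). The list's median log2 change was -2.75 (camera, Benjamini-Hochberg adjusted p = 7.66e-26, and adjusted p = 0.343 with an estimated correlation). Dtl, which controls replication licensing, fell from 745 ± 92.0 (SD, n = 2) to 14.2 ± 0.855 (SD, n = 2), and Clspn, a checkpoint adaptor, by a log2 change of -5.13. Of 52 genes of G2 and M phase, 50 fell and 1 rose, the same numbers as adjusted over the list alone. The median change was -4.17 (camera, Benjamini-Hochberg adjusted p = 1.7e-34, and adjusted p = 0.343 with an estimated correlation). Ccnb1, the mitotic cyclin B1, fell from 1286 ± 97.1 (SD, n = 2) to 28.6 ± 7.43 (SD, n = 2), and Plk1, a mitotic kinase, from 574 ± 16.1 (SD, n = 2) to 16.7 ± 0.678 (SD, n = 2). The member that rose was Tubb4b, a tubulin gene, by 0.51; of the 8 fits with a library left out, only the 2 without a P6 library kept that call.

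Some adult heart muscle genes rose and some fetal isoforms fell. Of 33 adult heart muscle genes 17 rose, the same count as adjusted over the list alone. Members had a median of 0.69 (camera, Benjamini-Hochberg adjusted p = 6.31e-05, and adjusted p = 0.539 with an estimated correlation). Ckmt2, the mitochondrial creatine kinase of muscle, rose from 6459 ± 1417 (SD, n = 2) to 71840 ± 203 (SD, n = 2) (log2 change 3.49 ± 0.25 (SE); limma, BH-adjusted p = 1.29e-05). Cox7a1, the muscle subunit of cytochrome c oxidase, rose by 2.39. After quantile normalization 12 of the 33 rose and 2 fell. Of 22 fetal and neonatal isoforms 11 fell and 1 rose (the same adjusted over the list alone). The median of the list was -0.86 (camera, Benjamini-Hochberg adjusted p = 0.00145, and adjusted p = 0.343 with an estimated correlation). Myh7, the slow myosin heavy chain of the fetal ventricle, fell from 53940 ± 13010 (SD, n = 2) to 5227 ± 339.8 (SD, n = 2). Nppb, which encodes a natriuretic peptide, rose by 0.70, a call lost without either library of P3 or of P24 (log2 change 0.57 to 0.82 over the fits). Several members of this list are also expressed in atria, and 3 atrial genes chosen after their values were seen differed between replicates: Myl7 lay at 4004 and 52 in the P3 libraries and 17 and 708 in the P6 libraries, Sln at 254 and 0 and at 0 and 79, and Myl4 at 2999 and 425 and at 212 and 919. Of 46 calcium handling and ion channel genes 19 rose and 8 fell (19 and 10 adjusted over the list alone), and the median of 0.29 lay at -0.05 when scaled by library size alone (camera, Benjamini-Hochberg adjusted p = 0.0677, and adjusted p = 0.75 with an estimated correlation). Kcnd3, a subunit of the transient outward potassium channel, rose from 41.3 ± 2.79 (SD, n = 2) to 662 ± 3.03 (SD, n = 2), Scn4b, a sodium channel subunit, rose by 3.95, and the potassium channel subunit Kcne1 fell from 6288 ± 747 (SD, n = 2) to 916 ± 203 (SD, n = 2).

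**Figure D1:**
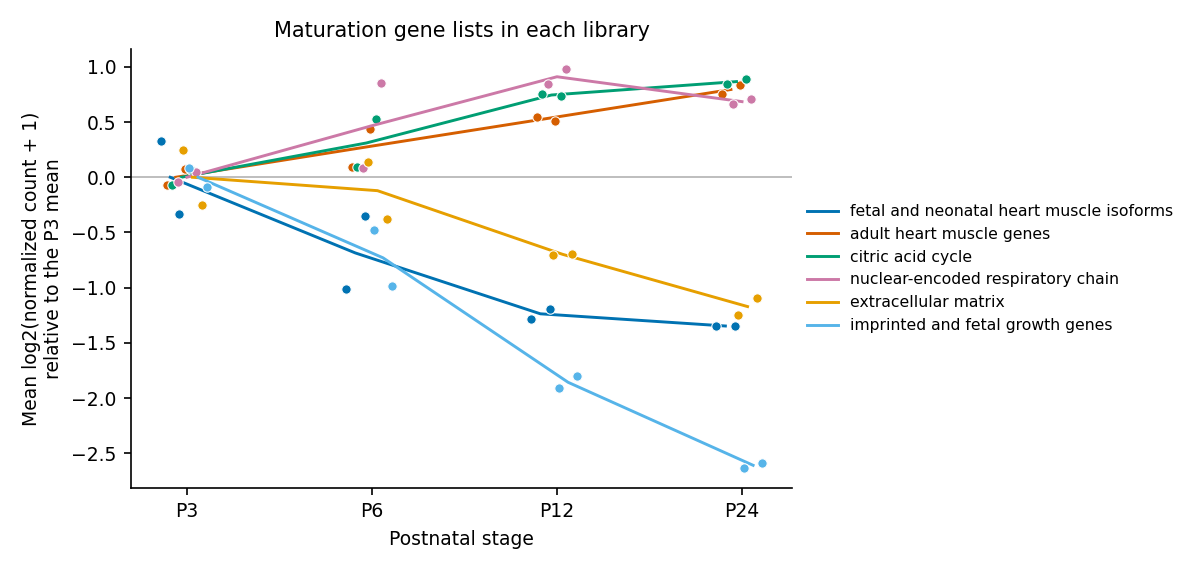
Mean log2(normalized count + 1) of 6 gene lists in each library (points), relative to the P3 mean of the list, with lines through the means of the 2 libraries of a stage. The imprinted and fetal growth genes reached -2.63 and -2.59 in the P24 libraries, and the respiratory chain list lay at 0.08 and 0.854 in the P6 libraries.

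Many genes of mitochondrial energy metabolism rose from P3 to P24. Of 26 citric acid cycle genes 22 rose (24 adjusted over the list alone). The list had a median of 0.77 (camera, Benjamini-Hochberg adjusted p = 1.8e-07, and adjusted p = 0.573 with an estimated correlation). Mpc1, a subunit of the mitochondrial pyruvate carrier, rose from 2194 ± 45.6 (SD, n = 2) to 8830 ± 42.5 (SD, n = 2), and Sucla2, a subunit of succinyl-CoA ligase, by 1.30. Of 70 nuclear genes of the respiratory chain 38 rose (47 adjusted over the list alone). The group's median was 0.72 (camera, Benjamini-Hochberg adjusted p = 4.65e-09, and adjusted p = 0.734 with an estimated correlation). Uqcrc1, a core subunit of complex III, rose by 1.18, and Uqcrfs1, its iron-sulfur protein, by 1.11. Scaled by library size alone, 12 citric acid cycle genes rose, and 12 of the respiratory chain genes rose and 1 fell; after quantile normalization these numbers were 10, 27 and 1. Of 11 measured mitochondrially encoded messenger RNAs 9 rose, the same count as adjusted over the list alone. The list's median log2 change was 1.11 (camera, Benjamini-Hochberg adjusted p = 0.0017, and adjusted p = 0.535 with an estimated correlation). After quantile normalization 3 rose, but that method gives every library the same distribution of values. It can remove a rise of the most abundant transcripts, so for the most abundant of these messages that count cannot decide. mt-Nd2 rose from 122900 ± 658 (SD, n = 2) to 407700 ± 5928 (SD, n = 2), and mt-Atp6, far lower, from 33.8 ± 1.58 (SD, n = 2) to 103 ± 8.90 (SD, n = 2). mt-Co2 lay between 66 and 3966 in single libraries, and reads of these genes may be shared with nuclear copies. Mitochondrially encoded transcripts held 9.64% and 10.7% of reads at P3 and 18.78% and 18.96% at P24. Of 43 fatty acid oxidation genes 19 rose and 4 fell (the same adjusted over the list alone). The median change was 0.49 (camera, Benjamini-Hochberg adjusted p = 0.00199, and adjusted p = 0.585 with an estimated correlation). In contrast, 11 rose and 7 fell when scaled by library size alone. Dgat2, which makes triglyceride, rose by 2.17 and Acad11, an acyl-CoA dehydrogenase, by 1.85. The members that fell were the thioesterase genes Acot1 and Acot2, near-identical copies whose reads may be shared, Cpt1a, the fetal and liver form of carnitine palmitoyltransferase, at -1.05, and Ucp2, an uncoupling protein, at -0.83. Of 29 glycolysis and lactate genes 9 rose and 6 fell (the same adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.686, and adjusted p = 0.853 with an estimated correlation): Pfkfb2 rose by 2.09 and Slc2a4, the insulin-responsive glucose transporter, by 1.59, whereas Aldoc, a brain-type aldolase, fell (log2 change -4.77), as did the kinase gene Pdk3 (-3.08).

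Most fetal growth genes and many matrix genes fell from P3 to P24. Of 49 extracellular matrix genes 26 fell and 3 rose (27 and 3 adjusted over the list alone). Members had a median of -0.92 (camera, Benjamini-Hochberg adjusted p = 1.92e-06, and adjusted p = 0.626 with an estimated correlation). Postn, periostin of activated fibroblasts, fell from 36920 ± 5111 (SD, n = 2) to 2184 ± 162 (SD, n = 2) and Col11a1, a fibrillar collagen, from 402 ± 48.7 (SD, n = 2) to 9.47 ± 5.73 (SD, n = 2), whereas Cilp rose by 2.12, Col8a1 by 2.10 and Dcn, decorin, by 1.07. Replicates of the younger stages differed in collagen: Col1a1 lay at 37990 and 11770 at P3, 27700 and 6194 at P6, 5117 and 5145 at P12 and 3860 and 4095 at P24, and its fall was not called without P3 replicate 1 or either P24 library (log2 change -3.26 to -1.56 over the fits). Of 22 imprinted and fetal growth genes 19 fell and 1 rose (20 and 1 adjusted over the list alone). The median of the list was -2.31 (camera, Benjamini-Hochberg adjusted p = 8.67e-10, and adjusted p = 0.368 with an estimated correlation). The member that rose, Zrsr1, an imprinted splicing factor gene, did so by 1.25.

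Most genes of antigen presentation, interferon response and macrophages rose. Of 15 antigen presentation genes 14 rose (15 adjusted over the list alone). The list had a median of 1.96 (camera, Benjamini-Hochberg adjusted p = 1.66e-09, and adjusted p = 0.343 with an estimated correlation). H2-Aa, of MHC class II, rose from 46.8 ± 7.96 (SD, n = 2) to 779.6 ± 158 (SD, n = 2), and Cd74, the class II invariant chain, from 111 ± 27.7 (SD, n = 2) to 1758 ± 309 (SD, n = 2). Of 25 interferon response genes 22 rose (23 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 7.45e-09, and adjusted p = 0.507 with an estimated correlation). Scaled by library size alone 16 rose and 1 fell. Markers of macrophages moved with both lists: 14 of 18 rose (17 adjusted over the list alone). The list's median log2 change was 1.44 (camera, Benjamini-Hochberg adjusted p = 3.81e-08, and adjusted p = 0.368 with an estimated correlation). Among them were Timd4 at 4.58 and Cd163 at 4.27, both marks of resident macrophages. The list of lymphocyte and granulocyte markers did not pass, with a median of 0.02 and a mean of -0.26 (camera, direction down, Benjamini-Hochberg adjusted p = 0.891, and adjusted p = 0.945 with an estimated correlation).

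At the first step, from P3 to P6, few single genes passed the threshold. The P6 libraries nevertheless lay at 21.2% and 25.3% of the course from P3 to P24. These are medians over 2924 genes that changed at least 2-fold over that span in a fit without P6. Rxrg (ENSMUSG00000015843), the retinoid X receptor gamma, rose from 157 ± 8.34 (SD, n = 2) to 792 ± 119 (SD, n = 2), a log2 change of 2.32 ± 0.15 (SE) (limma, BH-adjusted p = 0.000384). Myh7 fell from 53940 ± 13010 (SD, n = 2) to 4823 ± 1000 (SD, n = 2), a log2 change of -3.48 (limma, BH-adjusted p = 0.000361). Klhl33 and Klhdc8a, of the kelch repeat family, rose from 23.6 ± 2.46 to 158 ± 2.67 and from 143 ± 4.88 to 924 ± 133, and Pi16, a fibroblast marker, rose from 287 ± 11.3 (SD, n = 2) to 1272 ± 89.0 (SD, n = 2). Those 5 were the calls among the 21 named ones of this step that held in all 8 fits with a library left out. Hmcn2, a matrix protein gene, rose by 3.12, and Art1, an ADP-ribosyltransferase of muscle, by 2.24. Cdh3, a cadherin, fell (log2 change -2.29), as did the hypoxia-inducible factor gene Hif3a (-2.29), Plppr1 (-1.99) and Hey2, a transcription factor of the compact ventricular wall (-1.85). In all 118 of 14055 genes changed, 92 rising and 26 falling, and 2133 had an unadjusted p below 0.05.

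Lists shifted from P3 to P6 mostly without single calls. S phase genes had a median log2 change of -0.70 (camera, Benjamini-Hochberg adjusted p = 4.36e-22, and adjusted p = 0.368 with an estimated correlation). Of its 48 members 3 fell (32 adjusted over the list alone), namely Dtl at -1.12, Mcm2 at -0.97 and Mcm4 at -0.87, the last 2 being subunits of the replicative helicase. G2 and M phase genes had a median of -0.27 (camera, Benjamini-Hochberg adjusted p = 1.89e-06, and adjusted p = 0.585 with an estimated correlation). Of 22 imprinted and fetal growth genes Dlk1 and Plagl1 fell (13 adjusted over the list alone). The median change was -0.79 (camera, Benjamini-Hochberg adjusted p = 2.28e-07, and adjusted p = 0.507 with an estimated correlation). Fetal and neonatal isoforms had a median of -0.62 with Myh7 as the 1 call (5 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 9.56e-05, and adjusted p = 0.343 with an estimated correlation). The atrial marker list averaged 1.09 and -1.09 in the P3 libraries and -1.92 and -0.28 in the P6 libraries, relative to the P3 mean. Of 13 fibroblast markers Pi16, Mfap5 and Medag rose (4 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 2.62e-05, and adjusted p = 0.507 with an estimated correlation). Respiratory chain genes had a median of 0.47 (camera, Benjamini-Hochberg adjusted p = 4.45e-14, and adjusted p = 0.626 with an estimated correlation). With the length trend removed, this list's median was 0.373. The list averaged 0.08 in P6 replicate 1 and 0.854 in P6 replicate 2, relative to the P3 mean, and the same libraries differed by gene length: the shortest 10% of genes lay at -0.26 and 0.32 relative to each gene's mean, the longest 10% at 0.26 and -0.22. Leaving out 1 library gave 6 and 9 without P3 replicates 1 and 2, 4443 and 970 without P6 replicates 1 and 2, 18 and 18 without P12 replicates 1 and 2, and 12 and 13 without P24 replicates 1 and 2. Scaling by library size alone gave 64 calls, no filter 70, DESeq2 504 (60.7% rising against 78%), limma-voom 112 (67% rising), removal of the length trend 304 (67.1% rising) and of the length and GC trends 385. A fit without the 2 libraries with high atrial genes, which leaves 1 library each at P3 and P6 and takes the spread from P12 and P24, gave 1355, a test against a log2 change of 1 gave 5, and limma on only the 4 libraries of P3 and P6 0 (1106 at an unadjusted p below 0.05).

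From P6 to P12 a fetal troponin gene and some fetal growth genes fell. Tnni1 fell from 33050 ± 16990 (SD, n = 2) to 2042 ± 1634 (SD, n = 2), a log2 change of -4.19 ± 0.54 (SE) (limma, BH-adjusted p = 0.0125). Cemip, a hyaluronan-degrading protein gene, fell (log2 change -2.89), as did Bex4 (-2.53), Inhba, a subunit of activin (-2.46), and Col11a1 (-2.46). Pnpla3, a lipase of lipid droplets, rose by 2.72, Cbr2, a carbonyl reductase, by 2.51, Art1 by 2.48 and Lypd8l by 4.71. Of 22 imprinted and fetal growth genes 7 fell (16 adjusted over the list alone). Members had a median of -0.90 (camera, Benjamini-Hochberg adjusted p = 9.68e-12, and adjusted p = 0.343 with an estimated correlation). Leading members were Dlk1 at -2.33 and Igf2, insulin-like growth factor 2, at -1.97. Of 49 matrix genes Col11a1, Vcan and Postn fell and Cilp rose (14 and 2 adjusted over the list alone). The median of the list was -0.47 (camera, Benjamini-Hochberg adjusted p = 2.14e-07, and adjusted p = 0.626 with an estimated correlation). Macrophage markers had a median of 0.71 (camera, Benjamini-Hochberg adjusted p = 4.1e-10, and adjusted p = 0.343 with an estimated correlation), with Cd14, C1qa and C1qc, the last 2 of the complement system, rising (11 adjusted over the list alone). Interferon genes had a median of 0.60 (camera, Benjamini-Hochberg adjusted p = 1.64e-09, and adjusted p = 0.507 with an estimated correlation), with Oas2 rising (12 adjusted over the list alone).

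In all 317 of 14055 genes changed from P6 to P12, 140 rising and 177 falling, and 2626 had an unadjusted p below 0.05. Citric acid cycle and respiratory chain genes had medians of 0.43 (camera, Benjamini-Hochberg adjusted p = 3.81e-08, and adjusted p = 0.539 with an estimated correlation) and 0.48 (camera, Benjamini-Hochberg adjusted p = 3.64e-13, and adjusted p = 0.636 with an estimated correlation). In the respiratory chain list P6 replicate 2 already lay near the P12 level. Relative to P3 this list averaged 0.08 and 0.854 in the P6 libraries and 0.842 and 0.979 in the P12 libraries. For the citric acid cycle these means were 0.092 and 0.529, and 0.753 and 0.737. P6 replicate 2 also resembled the P12 libraries by gene length. Relative to each gene's mean, the shortest genes lay at -0.263 and 0.324 in the P6 libraries and 0.156 and 0.281 in the P12 libraries. With the length trend removed, the P6 to P12 median was 0.308 for the respiratory chain and 0.416 for the citric acid cycle. Aldoc fell (log2 change -2.49), as did Pdk3 (-1.10), while Casq1, a calcium-binding protein of the sarcoplasmic reticulum, rose by 1.98. None of the 39 named calls held in all 8 fits with a library left out. Those fits gave 127 and 117 without P3 replicates 1 and 2, 776 and 5728 without P6 replicates 1 and 2, 0 and 13 without P12 replicates 1 and 2, and 95 and 94 without P24 replicates 1 and 2; at the count of 0, limma had 1383 genes with an unadjusted p below 0.05, and with all libraries edgeR called 347 and DESeq2 860. No filter gave 189 calls, a term for Y-linked reads 480, removal of the length trend 585 and of the length and GC trends 685, and a fit without the 2 libraries with high atrial genes 6189, whereas limma on only the 4 libraries of P6 and P12, and limma against a log2 change of 1, each gave 0 (1590 and 143 at an unadjusted p below 0.05).

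The step from P12 to P24 carried most of the fall in cell cycle transcripts. Ccnb1 went from 1069 ± 99.5 (SD, n = 2) to 28.6 ± 7.43 (SD, n = 2), a log2 change of -5.20 ± 0.23 (SE) (limma, BH-adjusted p = 2.71e-06). Sapcd2, Depdc1a and Fam83d, which act in mitosis, fell, with log2 changes of -5.20, -4.98 and -4.95. Of 52 G2 and M phase genes 48 fell, the same count as adjusted over the list alone. The list had a median of -3.78 (camera, Benjamini-Hochberg adjusted p = 4.38e-50, and adjusted p = 0.343 with an estimated correlation). Of 48 S phase genes 40 fell (43 adjusted over the list alone). The group's median was -1.89 (camera, Benjamini-Hochberg adjusted p = 1.66e-30, and adjusted p = 0.343 with an estimated correlation). Among them were Clspn at -4.15 and Exo1, an exonuclease, at -3.97. Tnni1 fell again (log2 change -5.73), while Myh7 rose by 0.77, Acta1, skeletal actin, by 0.85, Nppa, the atrial natriuretic peptide gene, by 1.47 and Hcn4, a pacemaker channel gene, by 1.01. Those 4 rises stood beside 7 falls among the 22 fetal and neonatal isoforms (5 and 7 adjusted over the list alone), a list with a median of 0.24 and a mean of -0.11 (camera, direction down, Benjamini-Hochberg adjusted p = 0.514, and adjusted p = 0.75 with an estimated correlation). With 1 library left out, the calls of Myh7, Acta1 and Hcn4 were lost in each fit without a P12 or P24 library, and that of Nppa without either P24 library (log2 change 0.86 to 2.07 over the 8 fits).

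**Figure D2:**
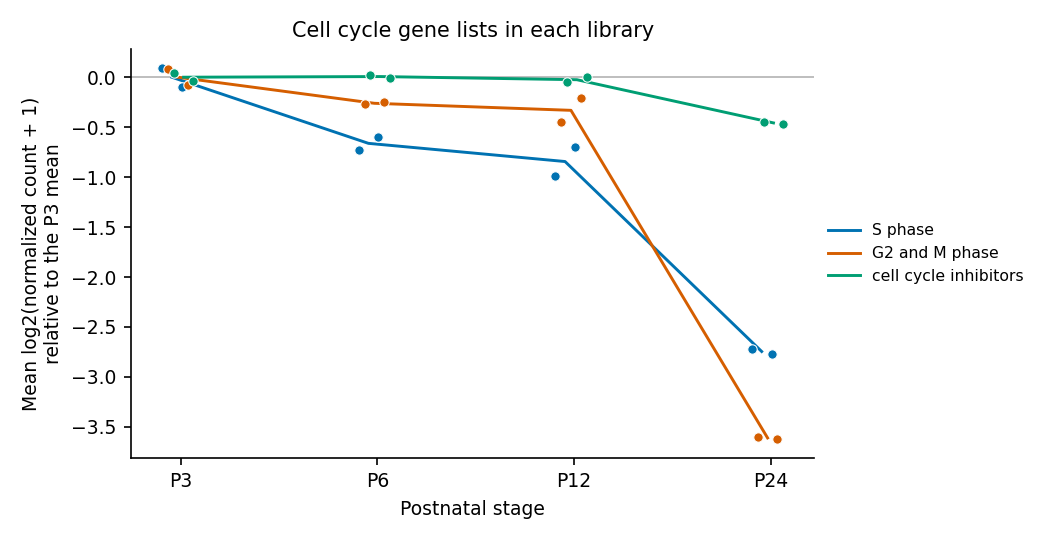
Mean log2(normalized count + 1) of 3 cell cycle lists in each library (points), relative to the P3 mean of the list, with lines through the stage means. G2 and M phase genes lay at -0.453 and -0.21 in the P12 libraries and at -3.6 and -3.62 in the P24 libraries.

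Ces1d rose from 150.3 ± 40.8 (SD, n = 2) to 4633 ± 424 (SD, n = 2) (log2 change 4.96 ± 0.56 (SE)), Gsta3, a glutathione transferase, from 17.2 ± 2.51 (SD, n = 2) to 305 ± 0.108 (SD, n = 2) and Kcnv2, a potassium channel subunit, from 8.55 ± 0.170 (SD, n = 2) to 202 ± 2.92 (SD, n = 2). Mmp3, a matrix metalloproteinase, reached 104 ± 30.8 (SD, n = 2) from 2.59 ± 2.30 (SD, n = 2), and Myoc, myocilin, 187 ± 15.5 (SD, n = 2) from 10.4 ± 9.20 (SD, n = 2). Of 15 antigen presentation genes 11 rose (12 adjusted over the list alone). The list's median log2 change was 0.97 (camera, Benjamini-Hochberg adjusted p = 4.67e-08, and adjusted p = 0.343 with an estimated correlation). Leading members were Cd74 at 3.12 and H2-Aa at 2.83. Of 18 macrophage markers 6 rose (9 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.000473, and adjusted p = 0.539 with an estimated correlation). Of 49 matrix genes 13 fell and 3 rose (15 and 3 adjusted over the list alone). The median change was -0.43 (camera, Benjamini-Hochberg adjusted p = 0.000396, and adjusted p = 0.734 with an estimated correlation). Postn fell (log2 change -3.20), as did Tnc, tenascin C (-1.99), whereas Comp rose by 1.70, Fbln1 by 1.26 and Timp3 by 0.76. Of 46 calcium handling and ion channel genes 12 rose and 4 fell (22 and 5 adjusted over the list alone). Members had a median of 0.43 (camera, Benjamini-Hochberg adjusted p = 0.00437, and adjusted p = 0.636 with an estimated correlation). However, 5 rose and 6 fell when scaled by library size alone. Kcnd3 rose by 2.15, Kcnj3 by 1.29, and Kcne1, Casq1, Fkbp1b and Gjc1 fell, Kcne1 at -2.63. Of 11 mitochondrially encoded messenger RNAs mt-Nd2, mt-Atp6 and mt-Nd4 rose (7 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0017, and adjusted p = 0.535 with an estimated correlation). The nuclear respiratory chain list, in contrast, had a median of -0.24 (camera, Benjamini-Hochberg adjusted p = 0.0162, and adjusted p = 0.825 with an estimated correlation), and its 1 call was Cox8a, a subunit of cytochrome c oxidase, which fell. Short genes shifted at this step as well. Relative to each gene's mean, the shortest 10% lay at 0.156 and 0.281 in the P12 libraries and -0.059 and -0.07 in the P24 libraries. With the length trend removed, the P12 to P24 median of the nuclear respiratory chain list was -0.066. In all 2297 of 14055 genes changed, 1153 rising and 1144 falling. Scaled by library size alone 499 of 2605 changed genes rose (19.2% against 50.2%), with the median gene shifted by -0.20. Leaving out 1 library gave 6031 and 6010 without P6 replicates 1 and 2, 1023 and 518 without P12 replicates 1 and 2, and 659 and 748 without P24 replicates 1 and 2. Without both P6 libraries 6022 genes were called, without the 2 libraries with high atrial genes 6591, with only the 4 libraries of P12 and P24 6631, and against a log2 change of 1 266. Of 115 named calls 43 held in all 8 fits with a library left out. Among those named here, the calls of Myoc and Fbln1 were lost without P12 replicate 2 or either P24 library, Timp3 in each fit without a P12 or P24 library, Kcnv2 without P12 replicate 2 and Casq1 without P24 replicate 1. The calls of mt-Nd2 and mt-Atp6 were lost without P12 replicate 2 or P24 replicate 1, and that of Cox8a was kept only without a P6 library.

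The retinoic acid lists, fixed for the signal that the title names, did not pass as lists in any of the 4 comparisons with camera, while single members changed. With fry the list of breakdown and retinal reduction passed from P12 to P24 (fry, Benjamini-Hochberg adjusted p = 0.0222) and from P3 to P24 (fry, Benjamini-Hochberg adjusted p = 0.0356). The other retinoic acid lists did not pass with fry in any comparison. Over all lists, fry passed 8 results that camera did not, and 30 that camera passed did not pass with fry. Rxrg rose at each step, from 157 ± 8.34 (SD, n = 2) at P3 to 792 ± 119 (SD, n = 2) at P6, 1683 ± 44.1 (SD, n = 2) at P12 and 2493 ± 139.6 (SD, n = 2) at P24, a log2 change of 3.98 ± 0.15 (SE) over the span (limma, BH-adjusted p = 8.44e-07). Aldh1a2 (ENSMUSG00000013584), the main retinoic acid-synthesizing enzyme of the embryonic heart, lay at 1650 ± 22.5 (SD, n = 2) at P3 and 2018 ± 119 (SD, n = 2) at P6, a difference of 0.29 that did not pass (limma, BH-adjusted p = 0.341), then fell to 1198 ± 74.9 (SD, n = 2) at P12 (limma, BH-adjusted p = 0.0265) and 387 ± 9.07 (SD, n = 2) at P24 (limma, BH-adjusted p = 7.47e-05). Aldh1a2 is also on the list of epicardial markers, of which 6 of 13 fell from P12 to P24 (6 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.00596, and adjusted p = 0.585 with an estimated correlation), Krt8 and Krt18 at -1.81 and -1.78. The call of Krt8 was lost without P12 replicate 2, and that of Krt18 without either P12 library or P24 replicate 2. Aldh1a1, another retinaldehyde dehydrogenase, rose from 156 ± 38.7 (SD, n = 2) to 570.4 ± 78.6 (SD, n = 2) (limma, BH-adjusted p = 0.000401), and Lrat, which esterifies retinol for storage, from 4.78 ± 3.68 (SD, n = 2) to 88.5 ± 5.14 (SD, n = 2). Dhrs3, which reduces retinal to retinol, rose from 622 ± 44.6 (SD, n = 2) to 1498 ± 58.7 (SD, n = 2) (limma, BH-adjusted p = 0.000122). With 1 library left out, the rise of Rxrg from P6 to P12 was lost without P12 replicate 1 or 2 (log2 change 0.94 to 1.25 over the 8 fits), and its rise from P12 to P24 in the 6 fits without a P3, P12 or P24 library (0.51 to 0.62). The fall of Aldh1a2 from P6 to P12 was lost in the same 6 fits (-0.81 to -0.69), while its later fall and the rises of Rxrg from P3 to P6 and from P3 to P24 were called in all 8.

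**Figure D3:**
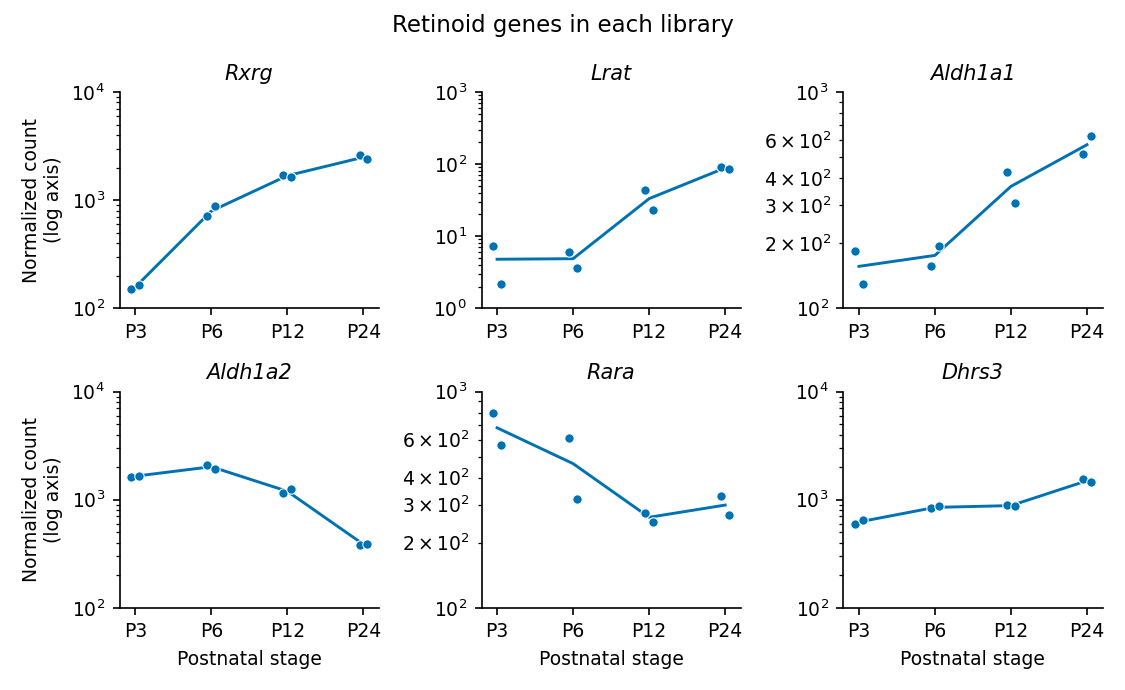
Normalized counts of 6 retinoid genes in each library (points; logarithmic axes) with lines through the means of the 2 libraries at P3, P6, P12 and P24. Rxrg rose at each step, to 2493 ± 139.6 at P24, and Aldh1a2 fell after P6, to 387 ± 9.07.

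Over the span from P3 to P24, 5 of 15 genes of retinoid uptake and retinoic acid synthesis rose and 4 fell (5 and 5 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.655, and adjusted p = 0.822 with an estimated correlation). Beside Lrat and Aldh1a1 they included Lpl, lipoprotein lipase, at 1.77, the dehydrogenase genes Adh1 at 1.63 and Rdh5 at 0.98, and in the other direction Aldh1a2 at -2.09, Rdh11 at -1.06 and Aldh1a3 at -0.81. Of 7 genes of breakdown and retinal reduction Dhrs3 rose (1 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.414, and adjusted p = 0.685 with an estimated correlation). Cyp26b1, a retinoic acid hydroxylase, lay at 35.9 ± 5.83 (SD, n = 2) at P12 and 75.4 ± 20.4 (SD, n = 2) at P24, which did not pass (limma, BH-adjusted p = 0.0665). Of 14 binding proteins and receptors Rxrg and Nr2f1 rose and Fabp5 and Rara fell (the same numbers adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.522, and adjusted p = 0.822 with an estimated correlation). Rara, the retinoic acid receptor alpha, went from 679.9 ± 160.3 (SD, n = 2) to 299 ± 43.2 (SD, n = 2), a call lost without P3 replicate 1 or P24 replicate 2. Rarb, a receptor gene induced by retinoic acid, lay at 271 ± 13.2 (SD, n = 2) at P3 and 319 ± 31.1 (SD, n = 2) at P24, a difference of 0.23 that did not pass (limma, BH-adjusted p = 0.328) and lay at -0.12 when scaled by library size alone. Of 21 target genes 3 rose, namely Lrat, Dhrs3 and Nr2f1, and 4 fell, among them Ucp2, Gata4 and Tgm2 (3 and 4 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.583, and adjusted p = 0.822 with an estimated correlation). The 3 that rose are also on the other retinoic acid lists and were counted there. Over all tested genes 36.91% changed from P3 to P24. With 1 library left out, the calls of Nr2f1, Gata4 and Tgm2 were kept only in the 2 fits without a P6 library, that of Ucp2 was lost without either library of P3 or of P24, and that of Aldh1a3 without P3 replicate 1 or P24 replicate 2.

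Cell cycle inhibitors went both ways. From P3 to P24, 5 of 20 rose and 7 fell (5 and 10 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.162, and adjusted p = 0.539 with an estimated correlation). With fry, the test of whether the members move together, the list passed from P3 to P24 (fry, Benjamini-Hochberg adjusted p = 0.00319) and from P12 to P24 (fry, Benjamini-Hochberg adjusted p = 0.0036). Gadd45a, a stress-induced inhibitor of growth, rose at the first steps, from 148 ± 19.5 (SD, n = 2) at P3 to 343 ± 39.4 (SD, n = 2) at P6 and 699.5 ± 95.6 (SD, n = 2) at P12, steps that were each called in only the 2 fits without a P6 library among the 8 with a library left out. Rbl1, a relative of the retinoblastoma protein, fell from 863 ± 36.8 (SD, n = 2) to 175 ± 20.2 (SD, n = 2), and Wee1, a kinase that holds back mitosis, from 1333 ± 142 (SD, n = 2) to 329 ± 14.9 (SD, n = 2). From P12 to P24, 6 fell and Rbl2 rose (7 and 3 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0917, and adjusted p = 0.535 with an estimated correlation), with Cdkn2c (p18) at -1.53 and Cdkn2d (p19) at -1.54. The call of Cdkn2d was lost without P12 replicate 2, and that of Rbl2 was kept only without a P6 library. Cdkn1a (p21) lay at 1026 ± 17.7 (SD, n = 2) at P3 and 717 ± 250.5 (SD, n = 2) at P24, and Cdkn1b (p27) at 1917 ± 97.0 (SD, n = 2) and 1915 ± 8.47 (SD, n = 2), neither past the threshold.

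Fewer genes met the peak or trough rule, which needs 2 contrasts past the threshold, than changed from P3 to P24, which needs 1. Peak genes, higher at P6 or P12 than at both ends, numbered 100, of which 98 peaked at P12 and 4 at P6, with 2 at both. Among peak genes with a mean of at least 100 in 1 of the stages, Casq1 had the largest smaller difference, at 476 ± 119.8 (SD, n = 2) at P3, 1586 ± 275 (SD, n = 2) at P12 and 581 ± 153 (SD, n = 2) at P24. The next were the microfibril genes Mfap5, with 3083 ± 117 (SD, n = 2) at P12 against 1159 ± 102 (SD, n = 2) and 1041 ± 4.69 (SD, n = 2) at P3 and P24, and Mfap4, with 3965 ± 209 (SD, n = 2) against 1586 ± 546 (SD, n = 2) and 449 ± 15.8 (SD, n = 2). Fam110d, Thy1, Higd1b, BC028528, Gask1a, Meox1 and Pamr1 followed under the same limit. The P3 to P12 and P12 to P24 calls of Mfap5, Thy1 and Meox1 held in all 8 fits with a library left out. Each of the other peak genes named here lost 1 or both of these calls in some fit. The P12 to P24 call of Higd1b was kept only in the 2 fits without a P6 library. That of Gask1a was lost in each fit without a P12 or P24 library. Mfap5 and Mfap4 are on the list of fibroblast markers and Higd1b on that of mural cells. Trough genes numbered 148, all of them at P12. Myh7 had its lowest mean there, at 3058 ± 39.6 (SD, n = 2), as did Nppa, at 1022 ± 572 (SD, n = 2) against 3555 ± 19.2 (SD, n = 2) at P3 and 2593 ± 34.3 (SD, n = 2) at P24, Acta1, at 1173 ± 23.1 (SD, n = 2), and the giant sarcomere protein gene Ttn. Endocardial and atrial markers moved with them, and Npr3 and Plvap of the endocardial list and Nppa and Stard10 of the atrial list were themselves trough genes. Relative to P3 the endocardial list averaged -1.06 and -1.19 in the P12 libraries and -0.42 and -0.41 in the P24 libraries, and the atrial list -2.10 and -2.36, and -1.32 and -1.46. From P6 to P12, 2 of 7 endocardial markers fell, Tmem108 and Cgnl1 (4 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.000681, and adjusted p = 0.539 with an estimated correlation). From P12 to P24, 3 rose, Npr3, Cytl1 and Plvap (3 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.0193, and adjusted p = 0.626 with an estimated correlation). The P12 to P24 calls of Npr3, Cytl1, Plvap and Stard10 were lost in each fit that left out a P12 or P24 library, and so was the P6 to P12 call of Tmem108. The P12 to P24 call of Ttn and the P6 to P12 call of Cgnl1 were kept only in the 2 fits without a P6 library. The atrial list had a median of -1.11 from P6 to P12 (camera, Benjamini-Hochberg adjusted p = 0.00471, and adjusted p = 0.539 with an estimated correlation) and 0.85 from P12 to P24 (camera, Benjamini-Hochberg adjusted p = 0.171, and adjusted p = 0.685 with an estimated correlation). Its P6 to P12 fall did not pass with fry (fry, Benjamini-Hochberg adjusted p = 0.108). Relative to P3 the list averaged -1.918 in P6 replicate 1, already near the P12 level, and -0.279 in P6 replicate 2, so most of that fall came from replicate 2. Of the trough genes 112 (75.7%) were longer than the median tested gene, and of the peak genes 26 (26%), while the rank correlation across genes of length with the change was -0.339 from P3 to P12 and 0.282 from P12 to P24; genes are not independent replicates. With library size alone as the scaling there were 63 trough genes, 46 of them shared, with DESeq2 234 and with a term for Y-linked reads 327. Peak genes numbered 154 with DESeq2, 171 with the Y-linked term and 174 without the length and GC trends. A fit without the 2 libraries with high atrial genes gave 1018 peak and 1246 trough genes. Without 1 library the peak genes numbered 18 and 29 without P3 replicates 1 and 2, 1224 and 955 without P6 replicates 1 and 2, 6 and 6 without P12 replicates 1 and 2, and 15 and 21 without P24 replicates 1 and 2. Trough genes in those fits numbered 21 and 44 without P3 replicates 1 and 2, 1516 and 1343 without P6 replicates 1 and 2, 19 and 8 without P12 replicates 1 and 2, and 12 and 17 without P24 replicates 1 and 2.

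**Figure D4:**
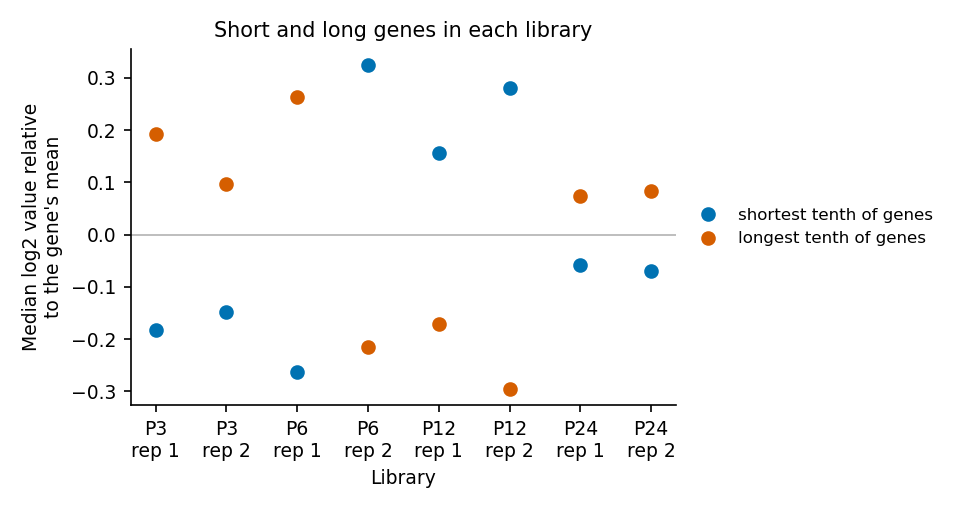
Median log2 value, relative to each gene's mean over all libraries, of the shortest 10% and the longest 10% of tested genes in each library. Short genes lay at -0.26 in P6 replicate 1 and 0.32 in P6 replicate 2, and long genes at 0.26 and -0.22.

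The peak and trough classes rest on 2 further contrasts. From P3 to P12, 3432 of 14055 genes changed, 1608 rising and 1824 falling; S phase genes fell in 29 of 48 cases and G2 and M phase genes in 8 of 52. From P6 to P24, 3749 changed, 1830 rising and 1919 falling. Scaled by library size alone 33.8% of the calls from P3 to P12 (46.9% before) and 23.9% of those from P6 to P24 (48.8% before) were rises, with median shifts of -0.14 and -0.26. With 1 library left out the P3 to P12 count was 901 and 1337 without P3 replicates 1 and 2, 7013 and 6995 without P6 replicates 1 and 2, 665 and 989 without P12 replicates 1 and 2, and 2214 and 2218 without P24 replicates 1 and 2, and the P6 to P24 count 6557 and 5957 without P6 replicates 1 and 2 and 1812 and 1890 without P24 replicates 1 and 2. The joint test over the stages called 4909 genes. Of those that changed from P3 to P24, 3151 changed in none of the successive steps, and 2537 genes changed in at least 1 step.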

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

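The settings with edgeR, Y-linked reads, the length and GC trends, both P6 libraries left out and the pair of libraries with high atrial genes left out were chosen after the data were seen. Over the counts of genes and lists, 111 alternative values lay within 1.5 times the reported value and 94 did not. With 1 library left out, where its partner is assumed to vary like the other stages, the counts ran from 6 to 4443 from P3 to P6, 0 to 5728 from P6 to P12, 518 to 6031 from P12 to P24, 665 to 7013 from P3 to P12, 1812 to 6557 from P6 to P24 and 3063 to 7822 from P3 to P24. For genes changed among the 4 stages they ran from 2385 to 9986, for peak genes from 6 to 1224 and for gene lists from 53 to 61. The highest counts of genes came without a P6 library, where the median standard error from P12 to P24 was 0.129 against 0.211 without a P3 library, so the spread of the P6 libraries enlarged the pooled error of the fit. The count of 0 from P6 to P12 came without P12 replicate 1 (limma, 1383 genes at an unadjusted p below 0.05).

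Without both P6 libraries the counts were 6022 from P12 to P24, 7009 from P3 to P12 and 7819 from P3 to P24. Without the pair with high atrial genes, where P3 and P6 keep 1 library each and the spread comes from P12 and P24, they were 1355 from P3 to P6, 6189 from P6 to P12, 6591 from P12 to P24, 5656 from P3 to P12, 6466 from P6 to P24, 9938 genes changed among the 4 stages and 1018 peak genes. With limma on only the 4 libraries of the stages compared, which leaves fewer degrees of freedom, the counts were 0 from P3 to P6 (1106 at an unadjusted p below 0.05, with 99 by edgeR and 504 by DESeq2 on all libraries), 0 from P6 to P12 (1590, 347 and 860), 6631 from P12 to P24, 6513 from P3 to P12 and 2044 from P6 to P24. The median standard error of these 4-library fits was 0.25 from P3 to P6, 0.243 from P6 to P12 and 0.24 from P6 to P24. It was 0.12 from P12 to P24 and 0.134 from P3 to P12, against 0.201 in the fit of all libraries. Fewer degrees of freedom alone thus do not account for the counts of 0. The calls with P6 in the main fit rest on an error shared with tighter stages. Against a log2 change of 1, a stricter question, limma called 5, 0, 266, 151, 600 and 1059 genes for P3 to P6, P6 to P12, P12 to P24, P3 to P12, P6 to P24 and P3 to P24.

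Other values beyond 1.5 times were, from P3 to P6, 64 with library size alone, 70 with no filter, 304 without the length trend and 385 without the length and GC trends. From P6 to P12 they were 189 with no filter, 480 with a term for Y-linked reads, 585 without the length trend and 685 without both trends. Peak genes numbered 154 with DESeq2, 171 with the Y-linked term and 174 without both trends. Apart from the P6 spread and the smaller fits, the cause of these differences was not tested. Replicate number as a block, which the labels do not tie to a litter or day, gave 512 genes from P6 to P12 with 151 peak and 341 trough genes, and the deviations of replicate 1 from the stage mean correlated at 0.143 to 0.324 among P3, P6 and P12 and at -0.139 to 0.034 with P24. Since not every pair lay above 0.1, the numbers were not taken to pair the libraries, and the former values are a hint only. The difference between replicates 1 and 2 also went with gene length at P3, P6 and P12 (rank correlations 0.179, 0.507 and 0.259) and not at P24 (-0.033). Y-linked reads were found in replicate 1 at P6 and P12, in replicate 2 at P24 and in neither library at P3. The correlations among P6, P12 and P24 have the signs of that pattern: 0.324 for P6 with P12, and -0.132 and -0.139 for these with P24. Pairing, Y-linked reads and this length trend were not told apart. Of the 59 gene list results, camera with an estimated correlation kept 0 and fry called 37, of which 29 were shared. The 30 lost with fry included the nuclear respiratory chain at each step and from P3 to P24 (fry, Benjamini-Hochberg adjusted p = 0.261, 0.261, 0.642 and 0.134). They also included the matrix list from P6 to P12 and P12 to P24 (fry, Benjamini-Hochberg adjusted p = 0.189 and 0.21). The G2 and M phase list from P3 to P6 was another (fry, Benjamini-Hochberg adjusted p = 0.149). Of 328 called changes of named genes, none reversed in the settings in which these genes were refitted, which did not include the stricter filter, the 4-library fits, the test against a log2 change of 1 or the fit without the libraries with high atrial genes; without both P6 libraries 268 could be compared. Of the 328, 286 stayed called with library size alone, and 176 to 328 with 1 library left out. The uncalled difference of Aldh1a1 from P3 to P6 ran from -0.072 without P3 replicate 2 to 0.436 without P3 replicate 1. Each of these fits keeps 1 P3 library, so the range shows the gap between the P3 libraries. The uncalled difference of Rarb from P3 to P24 was -0.12 with library size alone. That scaling shifted the median gene by -0.348 at this contrast, so the change of sign was not particular to Rarb.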

Other observations

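The tests of the length trend, of the developmental course and of sex for the P6 libraries were chosen after the result was seen. Some hormone response and clock genes changed as well. Of 20 thyroid and glucocorticoid response genes 6 rose from P12 to P24 (8 adjusted over the list alone). The median was 0.51 (camera, Benjamini-Hochberg adjusted p = 0.00592, and adjusted p = 0.585 with an estimated correlation). From P3 to P24, 8 rose and 4 fell (8 and 4 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.234, and adjusted p = 0.75 with an estimated correlation), and 7 rose and 7 fell when scaled by library size alone. Over the same span, 5 of 19 clock genes rose and 4 fell (5 and 4 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.414, and adjusted p = 0.822 with an estimated correlation). Arntl, which encodes BMAL1, rose from 234 ± 1.88 (SD, n = 2) to 1128 ± 60.7 (SD, n = 2), and Per3 fell from 1050 ± 3.42 (SD, n = 2) to 381 ± 63.3 (SD, n = 2). The hour of dissection is not given in the sources used here.

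Antioxidant genes rose from P3 to P24 in 11 of 25 cases and fell in 2 (11 and 2 adjusted over the list alone), with a median of 0.37 (camera, Benjamini-Hochberg adjusted p = 0.00917, and adjusted p = 0.535 with an estimated correlation). Scaled by library size alone 6 rose and 5 fell. The glutathione transferase gene Gstm1 rose from 831 ± 68.7 (SD, n = 2) to 3161 ± 226 (SD, n = 2).

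The P6 libraries lay far apart, with a median absolute log2 difference of 0.39 against 0.118 to 0.154 at the other stages. Removing each library's trend with gene length lowered this to 0.314, and removing the GC trend to 0.388, while the other stages lay at 0.116 to 0.152 without the length trend, so neither trend is likely to be the whole cause. The median position between P3 and P24 differed by 0.041 between the P6 libraries, against 0.033, 0.098 and 0.012 at P3, P12 and P24. Some lists put P6 replicate 2 later (imprinted genes -0.475 and -0.985, citric acid cycle 0.092 and 0.529). Others put P6 replicate 1 later (fetal and neonatal isoforms -1.016 and -0.355, S phase -0.726 and -0.598). The lists thus do not agree on which heart was further along. Without the length trend the positions differed by 1.8% of the course at P6, against 3%, 8.7% and 0.9% at P3, P12 and P24. The P12 pair differed more in position than the P6 pair but lay only 0.146 apart. This argues against position along the course as the whole cause, while a partial role stays open. The P12 and P24 pairs, each with 1 library with and 1 without Y-linked reads, lay at 0.146 and 0.118, no further apart than the P3 pair without such reads (0.154), which argues against sex as the whole cause. Part of the difference went with length (rank correlation across genes 0.507), while dissection and the animal itself stay open and were not tested.

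Genes lowest at P12 included Myh7, Nppa and Ttn, and 75.7% of the trough genes were longer than the median gene. Without the length trend 81.1% of them (120 of 148) were still trough genes, which argues against length as the whole cause. With 1 library left out the count was 21 and 44 without P3 replicates 1 and 2, 19 and 8 without P12 replicates 1 and 2, and 12 and 17 without P24 replicates 1 and 2, so it rests on each of these 6 libraries, and it was 1516 and 1343 without P6 replicates 1 and 2. Endocardial and atrial marker lists were also lowest at P12, so a change in the share of these tissues stays open and was not tested, as does a change within heart muscle cells.

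G2 and M phase genes held nearer their P3 level to P12 (median log2 change -0.36, 8 of 52 fell) while S phase genes dropped further (-0.93, 29 of 48 fell). The gap of 0.572 between the medians was 0.476 without the length trend, which argues against length as the whole cause. The bootstrap SD of 0.123 (2000 draws) is over genes, which are not independent replicates, so it does not measure the spread between libraries. Relative to P3, the P12 libraries averaged -0.453 and -0.21 for G2 and M phase and -0.99 and -0.698 for S phase. A candidate explanation is that some heart muscle cells still enter mitosis or become binucleate at P12 while fewer replicate DNA. These data hold no cell counts, so this was not tested, and dividing cells of other types stay open.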
